A study of Homo sapiens with 4 samples.

How the data were processed

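RNA expression was measured on 4 one-colour Affymetrix arrays of MCF-7 cells, 2 labelled vehicle and 2 labelled E2. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was made from it. The labels disagree on the time of siRNA before ligand, 24 h in one field and 48 h in another, and give 72 h of virus infection. The authors deposited 1 table of log2 values for 22277 probe sets. Their normalization is not given in the sources used here, so its scale is known only from the values, which run from 2.33 to 14.44. Array medians differed by 0.027 at most, which is below the tolerance of 0.1 set before the data were examined, so the deposited log2 values were kept. The lowest value, 2.33, is shared by 34.5% to 35.0% of probe sets on every array, and values there have no order.

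Probe sets were named through the platform annotation supplied with the values. Of 22215 probe sets that were not controls, 19064 had 1 gene symbol, 1043 several and 2108 none, and only those with 1 symbol were used. The Entrez identifiers of 19052 of these were found in the RefSeq gene table, and no symbol changed. Of 742 list symbols, 655 were measured. For each gene the probe set with the highest mean over all arrays was kept, giving 11963 genes, of which 2644 lay at the lowest value on every array. Other probe sets of a gene can differ, as given for NCOA1.

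E2 minus vehicle was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p below 0.05), with 2 residual degrees of freedom. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01. The test, the 28 lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes were named by 3 rules. The first takes the 12 largest rises and 12 largest falls among called genes with both E2 arrays on one side of both vehicle arrays and a group mean of at least 2.64, the median of the probe sets' means. Where fewer passed, places went to the smallest unadjusted p, with values only. The second takes the 3 members of each list with the smallest unadjusted p, and the third takes 13 genes whatever their values. The text names part of these. The same rule was repeated for the arrays numbered 2 against those numbered 1, a comparison chosen after seeing the data.

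Alternatives were quantile normalization, equal array medians, leaving out the 40% dimmest genes, leaving out each array in turn, the replicate number as a block, the mean of a gene's probe sets, all probe sets fitted, no intensity trend, a robust prior, other thresholds, camera with an estimated correlation and fry. Pseudocounts were not needed, since the table is on the log2 scale. Where an array was left out, the lone array of its group was assumed to vary like the other group. The fit was tested on simulated data for 11963 genes with the spread of these arrays. For the labelled comparison it called 0% of 200 genes changed by 1 on the log2 scale, 7.1% of those changed by 2 and 39.2% of those changed by 3, with 1.5 false calls on average when nothing changed. For the comparison of numbers it called 0.75%, 37.5% and 63.2% of such genes. With nothing changed, no simulated gene could have values identical within both groups but different between them. In the arrays 22 of the 30 genes called by label had such values, so 1.5 may understate the false calls there. Of the lists, only G2/M was shifted in simulations, which held no correlation between genes. Shifted by 0.5 it was called in 10 of 10 simulations in both comparisons. With nothing shifted, camera made 0 calls over all lists in 10 simulations for the labels and 1 call for the numbers. In the arrays themselves the estimated correlation of G2/M by label was 0.85, so false calls may be more frequent there. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.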

Results

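Gene expression was measured on 4 Affymetrix arrays hybridised with RNA from MCF-7 cells, a human breast adenocarcinoma line that makes estrogen receptor alpha (ERα, gene ESR1) and grows in response to estrogen. For all 4 arrays the cells had been infected with an adenovirus carrying estrogen receptor beta (ERβ, gene ESR2) at a multiplicity of infection of 50. They had also received 20 nM small interfering RNA against ERα, so that ERβ would be the main estrogen receptor left. The comparison was between groups of 2 arrays each: cells given 0.1% ethanol (vehicle) and cells given 10 nM estradiol (E2), each for 24 h. The question was which transcripts E2 regulates through ERβ. Arrays with empty virus or control siRNA were not analysed here, so the size of the knockdown and of the ERβ gain was not measured. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. With 2 arrays per group, their number limits the precision of every value.

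Receptor transcripts did not pass the test between the labels. The brightest ESR2 probe set read 13.34 ± 0.22 (log2, SD, n = 2) on the arrays labelled vehicle and 13.36 ± 0.11 (SD, n = 2) on those labelled E2. Of its other 4 probe sets, 2 lay at the lowest value of the table, 2.33, on all arrays, and the other two read from 10.93 to 11.57 and from 11.35 to 11.76. ESR1 stood at 7.59 and 7.18 on vehicle arrays 1 and 2, and at 7.87 and 7.18 on E2 arrays 1 and 2. Its difference, E2 minus vehicle, was 0.14 with a standard error of 0.35, within the spread between replicates. These are values of its brightest probe set. Its other 8 were dimmer, 2 of them at the lowest value on all arrays, and differed by -0.74 to 0.34, the lowest being a probe set at 2.75 and 3.39 on the vehicle arrays and 2.33 on both E2 arrays.

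Transcripts that estrogen is known to raise in MCF-7 cells did not pass the test between the labelled groups, but differed widely between arrays of the same label. GREB1, an estrogen-induced growth regulator, stood at 2.33 on vehicle array 1 and 6.26 on vehicle array 2, and at 2.45 on E2 array 1 and 5.69 on E2 array 2. PGR, the progesterone receptor, read 2.33 and 3.92 on the vehicle arrays and 2.34 and 4.76 on the E2 arrays. TFF1, a secreted trefoil peptide, read 10.61 and 12.77 on the vehicle arrays and 10.70 and 12.73 on the E2 arrays. MYC, a growth-promoting transcription factor, read 6.80 and 8.02 on the vehicle arrays and 6.89 and 7.96 on the E2 arrays. In these 4 genes the label difference was -0.23 for GREB1, 0.42 for PGR, 0.02 for TFF1 and 0.02 for MYC, each smaller than its standard error of 2.21, 1.25, 1.28 and 0.70. Because the arrays split by replicate number in this way, they are called arrays labelled vehicle or labelled E2, and all directions below rest on the labels.

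**Figure D1:**
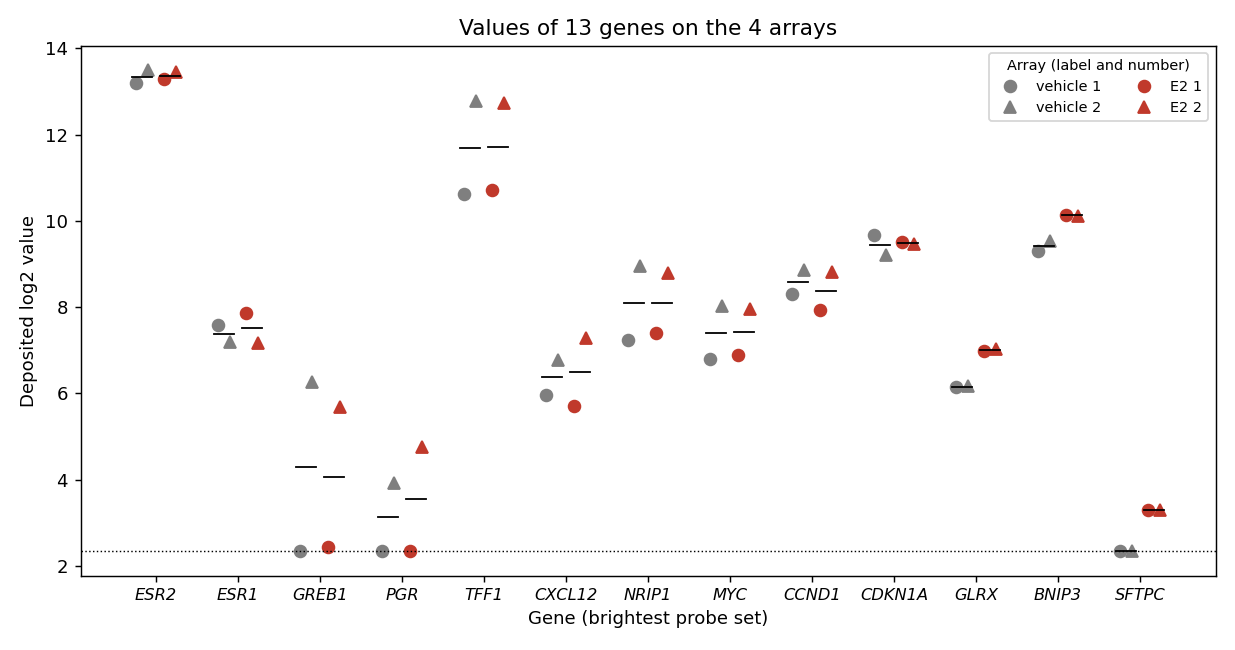
Deposited log2 values (vertical axis) of 13 genes (horizontal axis) on the arrays labelled vehicle (grey) and labelled E2 (red); circles are replicate number 1, triangles replicate number 2, black bars group means of 2 arrays, and the dotted line the lowest value of the table (2.33). GREB1, PGR, TFF1, NRIP1, MYC, CXCL12, CCND1 and ESR2 separate by replicate number, higher on number 2, and ESR1 and CDKN1A separate by it, lower on number 2. GLRX, BNIP3 and SFTPC, which were named for their results by label, separate by label.

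Of the other fixed genes, CXCL12, a chemokine, differed by 0.13 (standard error 0.77) between labels. NRIP1, a corepressor of nuclear receptors, differed by -0.01 (standard error 0.96). CCND1, cyclin D1, differed by -0.20 (standard error 0.46), and CDKN1A, a CDK inhibitor, by 0.04 (standard error 0.20). The coactivator NCOA2 differed by 0.09 (standard error 0.38). The coactivator NCOA1 was -1.05 (standard error 0.31) between labels, with an adjusted p of 1, and its other 3 probe sets read -0.72, -0.23 and -0.06. NCOA3 was not analysed here, for want of a probe set assigned to it alone.

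By limma's moderated test, 30 of 11963 genes passed an adjusted p of 0.05 between the labels, 12 higher and 18 lower on the arrays labelled E2. All 30 were dim and their replicates nearly or fully identical. In 29 of the 30 the higher group mean was below 3 on the log2 scale, in 22 the values were identical within both groups, and in 17 one group lay at the lowest value of the table, so that their differences are lower bounds in size. None differed 2-fold, and the median size of the difference was 0.09. The largest rise was that of SFTPC, a lung surfactant protein, from 2.33 on both vehicle arrays to 3.30 on both E2 arrays (adjusted p = 0.00209). BMP2K, a kinase, rose by 0.42 from 2.35, just above the lowest value (adjusted p = 0.00116). The cytokine IL5 rose by 0.35 (adjusted p = 0.00351), a lower bound since 1 vehicle array lay at the lowest value. NTRK3, a neurotrophin receptor, rose by 0.12 (adjusted p = 0.012). Among genes that fell, A4GALT, a glycosyltransferase, fell by 0.52 (adjusted p = 0.0115) and TBX6, a T-box transcription factor, fell by 0.39 (adjusted p = 0.00116).

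Brighter genes with tight replicates did not pass. GLRX, the redox enzyme glutaredoxin, read 6.16 ± 0.021 (SD, n = 2) on vehicle arrays and 7.01 ± 0.040 (SD, n = 2) on E2 arrays, a difference of 0.85 (adjusted p = 0.264 by limma). PHGDH, the first enzyme of serine synthesis, differed by 0.46 (adjusted p = 0.553), and the mitophagy gene BNIP3 by 0.71 (adjusted p = 1). The coregulator PHB2 differed by 0.26 (adjusted p = 1). Lower values on the E2 arrays included ITCH, a ubiquitin ligase, at -0.80 (adjusted p = 0.566), the kinase CSNK1G1 at -0.86 (adjusted p = 0.0766) and TCIM at -1.10 (adjusted p = 0.406). Among all genes, 338 had an unadjusted p below 0.05, and 28 differed at least 2-fold. Parting the arrays into pairs by neither label nor number gave 264 and 25. A share of 0.05 of all genes is 598, but the 2644 genes at the lowest value on every array cannot reach such a p. Fewer than 598 are thus expected if no gene differs. The difference by number also widens the spread that the label fit uses. By limma no gene passed without the 40% dimmest genes, with quantile normalization or with equal array medians, where 193, 288 and 201 genes had an unadjusted p below 0.05. The count was 107 without vehicle replicate 1, 151 without vehicle replicate 2, 138 without E2 replicate 1 and 199 without E2 replicate 2.

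**Figure D2:**
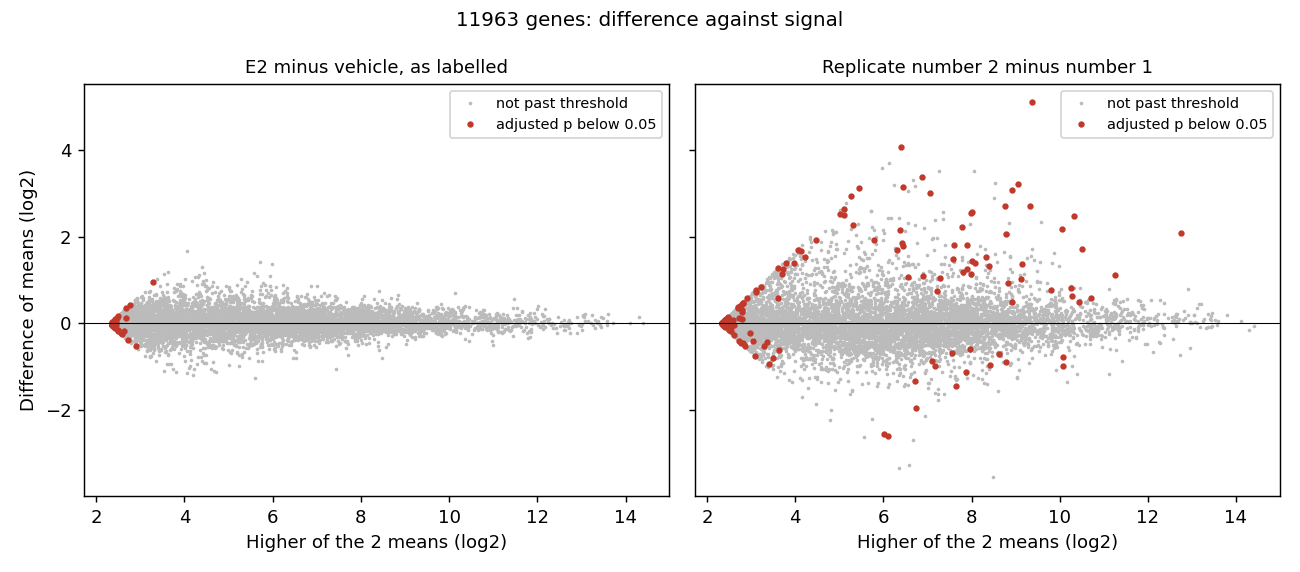
Difference of means (vertical axis, log2) against the higher of both means (horizontal axis, log2) for 11963 genes, by label on the left and by replicate number on the right; red points have an adjusted p below 0.05. The 30 genes called by label lie at the dim end, and the 146 called by number span the range of signal.

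None of the 28 fixed gene lists passed between labels by camera with a preset correlation (adjusted p from 0.134 to 0.975; 0.992 for every list with an estimated correlation), and 3 had an unadjusted p below 0.05. Fry called 1 list, glycolysis (adjusted p = 0.0433). Camera called 2 lists with equal array medians, 1 list without vehicle replicate 1 and 3 lists without each of the other arrays. The estrogen-induced list was then called up without E2 replicate 1 and down without E2 replicate 2. Leaving out 1 array left the replicate numbers unbalanced between the labels. The label difference then took in part of the difference by number, here and below. By number the estrogen-induced list had a median of 0.79, which pushes it in the directions called. Of 37 measured estrogen-induced genes, 19 read higher and 15 lower on the arrays labelled E2, none called, with a median difference of 0.003 and a mean of 0.056, while camera's direction was down. Of 26 estrogen-repressed genes, 13 read higher and 10 lower, none called, with a median of 0.02. The cell-cycle lists had medians of 0.01 over 42 genes of G1/S and DNA replication and 0.03 over 45 genes of G2/M and mitosis. These also turned with single arrays, in the directions that the imbalance of numbers gives. By number their medians were 0.97 for G1/S and 1.04 for G2/M. G2/M was called up without E2 replicate 1 and without vehicle replicate 2, and down without E2 replicate 2. G1/S was called up without E2 replicate 1 and without vehicle replicate 2. No camera call made between labels with equal array medians or without 1 array, here or below, held with an estimated correlation. The adjusted p was 0.745 with equal array medians. That version of camera could hardly call a list with so few arrays. By number it moved G1/S from an adjusted p of 9.48e-19 to 0.152, at an estimated correlation of -0.013, below the preset 0.01. Failing it thus decides nothing about a call where the estimate is near the preset. For the calls without 1 array the estimate was 0.74 for the estrogen-induced list, 0.69 and 0.77 for G1/S, and 0.83 and 0.96 for G2/M. If genes are so correlated, the preset of 0.01 makes p-values too small. The estimates were -0.04 for NF-kappaB, 0.01 for interferon response and 0.10 for MYC and immediate early genes.

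Among metabolic lists, glycolysis had a median of 0.09 over 22 genes, 14 higher and 5 lower, with an unadjusted camera p of 0.0048 and an adjusted p of 0.134. It was called up with equal array medians (adjusted p = 0.0215). The glycolytic enzymes PGAM1, PGK1 and TPI1, its members with the smallest unadjusted p, had log2 differences of 0.19, 0.26 and 0.20, and none was called. Oxidative phosphorylation had a median of 0.07 over 51 genes (adjusted p = 0.35), with NDUFA8 at -0.27 and UQCRC2 at 0.18. Medians were 0.10 for fatty acid synthesis, -0.07 for fatty acid oxidation, -0.02 for cholesterol synthesis and uptake and 0.01 for the tricarboxylic acid cycle. They were 0.05 for the pentose phosphate, serine and one-carbon list, -0.01 for nucleotide synthesis and 0.04 for glutamine and amino acid transport.

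NF-kappaB and inflammatory genes had a median of -0.08 over 25 genes, 3 higher and 17 lower, with an adjusted p of 0.134. The list was called down with equal array medians (adjusted p = 0.0174) and without vehicle replicate 1 (adjusted p = 0.0428). TNFAIP3, an inhibitor of NF-kappaB, read -0.57 and was not called. Interferon response genes had a median of -0.06 (adjusted p = 0.35), with the chemokine CXCL10 at -0.48. They were called down without vehicle replicate 2 (adjusted p = 0.0237). Medians of the stress and growth lists were 0.11 for hypoxia response, 0.10 for apoptosis regulators, 0.01 for the unfolded protein response, -0.02 for p53 targets, -0.06 for ribosome biogenesis and 0.00 for MYC and immediate early genes, which were called down without E2 replicate 2 (adjusted p = 0.0244). CDK inhibitors had a median of 0.06 although camera's direction was down. Adjusted over the list alone, 4 genes passed, APAF1 (0.35), CHAC1 (0.60), CDKN2B (-0.03) and CD3D (-0.02), of which CDKN2B and CD3D also passed over all genes.

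Markers of other cell types were tested as lists, and none of these lists passed between labels. Luminal epithelial markers had a median of 0.03 and basal or myoepithelial markers 0.11 over 11 genes (adjusted p = 0.873). The estrogen receptor and coregulator list and the epithelial-mesenchymal list each had a median of 0.00. Only 7 of 18 fibroblast and endothelial markers and 10 of 18 leukocyte markers lay above the lowest value on any array, so their medians of 0.00 say nothing of a difference. The leukocyte marker CD3D, called above, fell by 0.02. As a description of these arrays, label medians were set against 10000 random lists matched on mean expression. The lowest were those of NF-kappaB (percentile 0), interferon response (0.18), fatty acid oxidation (1) and ribosome biogenesis (2.5), leaving aside the fibroblast and leukocyte lists. The highest were those of basal markers (99.88), glycolysis (99.01), fatty acid synthesis (98.51), hypoxia response (98.18) and apoptosis regulators (98.06). Within number 1 and number 2 in turn, the label medians were 0.00 and 0.00 for NF-kappaB and -0.11 and 0.003 for interferon response. They were -0.001 and -0.05 for fatty acid oxidation and -0.02 and 0.03 for ribosome biogenesis. They were 0.09 and 0.11 for glycolysis, 0.04 and 0.07 for fatty acid synthesis, and 0.06 and 0.09 for hypoxia response. For apoptosis regulators they were 0.10 and 0.04, and for basal markers 0.00 and 0.02.

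**Figure D3:**
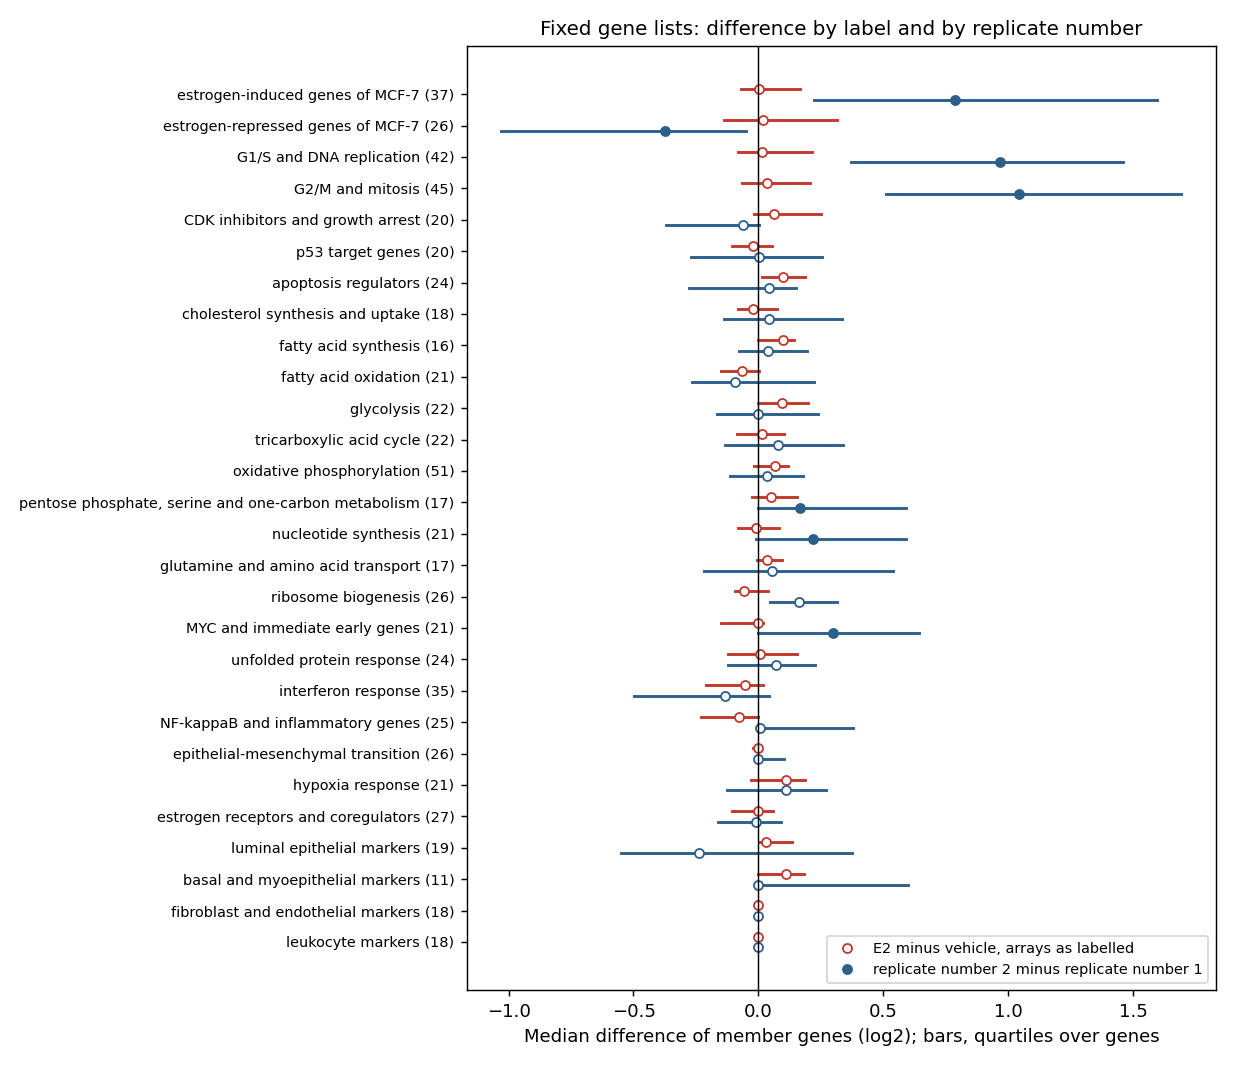
Median log2 difference (horizontal axis) of the members of each of 28 fixed gene lists (vertical axis, with the number of measured genes), by label in red and by replicate number in blue; bars run from the lower to the upper quartile over genes, and filled points have an adjusted camera p below 0.05. No list is filled by label, and 7 are filled by number.

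Arrays of the same number resembled each other more than arrays of the same label. Across genes, which are not independent replicates, Pearson's r was 0.9939 between the arrays numbered 1 and 0.9944 between those numbered 2. It was 0.982 between the vehicle arrays and 0.983 between the E2 arrays. Between vehicle array 1 and E2 array 1, 135 genes differed at least 2-fold, and 127 did between vehicle array 2 and E2 array 2. By contrast 634 genes differed that far between the vehicle arrays and 577 between the E2 arrays. The first principal component held 71.3% of the variance and separated the numbers.

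Fitted as the labels were, a comparison chosen after seeing the data, number 2 against number 1 called 146 genes, 104 higher and 42 lower on the arrays numbered 2, of which 59 differed at least 2-fold. The count was 0 with the label group as a block, where 1586 genes had an unadjusted p below 0.05. That fit left 1 residual degree of freedom, so its 0 does not show that the difference by number vanished. With equal array medians the count was 4775, with 690 higher and 4085 lower, and 2644 lay at the lowest value on all 4 arrays. It was 33 with a robust prior and 242 without the 40% dimmest genes. It was 324 without vehicle replicate 1, 370 without vehicle replicate 2, 298 without E2 replicate 1 and 351 without E2 replicate 2. The labels do not say what a number stands for. Of the 28 lists 7 passed by camera's preset correlation, and none with an estimated correlation (lowest adjusted p = 0.152), where 5 had an unadjusted p below 0.05. The estimated correlations of these 7 lay between -0.048 and 0.047, and that version could hardly call a list with 4 arrays. The estrogen-induced list had a median of 0.79 over 37 genes, 32 higher and 2 lower, of which 6 rose over all genes and 21 adjusted over the list alone (camera adjusted p = 3.1e-15; adjusted p = 0.152 with an estimated correlation). Among them IL17RB, a cytokine receptor, rose from 4.27 to 9.37, TFF1 from 10.66 to 12.75 and the chaperone HSPB8 from 6.06 to 8.77. The estrogen-repressed list had a median of -0.38 over 26 genes, 19 lower, of which 1 fell over all genes and 6 adjusted over the list alone (adjusted p = 0.000304; adjusted p = 0.242 with an estimated correlation). It was not called with equal array medians (adjusted p = 0.149). BIK, a pro-apoptotic factor, fell by 0.99.

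Cell-cycle genes were higher on the arrays numbered 2. The G2/M list had a median of 1.04, with 44 of 45 genes higher, 7 called over all genes and 32 adjusted over the list alone (adjusted p = 8.53e-24; adjusted p = 0.179 with an estimated correlation). PTTG1, securin, rose by 3.02. The G1/S list had a median of 0.97, with 39 of 42 genes higher and 7 called over all genes, and 25 adjusted over the list alone (adjusted p = 9.48e-19; adjusted p = 0.152 with an estimated correlation). CDC6, a replication licensing factor, rose by 2.49 and RFC3, a clamp loader subunit, by 2.07. Nucleotide synthesis had a median of 0.22 and RRM2, a subunit of ribonucleotide reductase, rose by 2.47 (list adjusted p = 0.000548; adjusted p = 0.242 with an estimated correlation). MYC and immediate early genes had a median of 0.30, and MYC rose by 1.15 (list adjusted p = 0.000304; adjusted p = 0.242 with an estimated correlation). The list was not called without E2 replicate 1 (adjusted p = 0.051). FOS rose from 2.33, the lowest value, on both arrays numbered 1 to 5.27 on those numbered 2, so that its difference of 2.93 is a lower bound. The pentose phosphate, serine and one-carbon list had a median of 0.17, with TYMS, thymidylate synthase, up by 0.59 (list adjusted p = 0.0148; adjusted p = 0.356 with an estimated correlation). It was not called without E2 replicate 1 (adjusted p = 0.0753) or without E2 replicate 2 (adjusted p = 0.101). RRM2 and TYMS are also members of the G1/S list. No other gene of the nucleotide and pentose phosphate lists was called over all genes, so these lists are not independent of G1/S. ESR1 was lower by number, at -0.55 (adjusted p = 0.233). Luminal epithelial markers had a median of -0.24 by number over 19 genes, 6 higher and 12 lower, and were not called as a list (adjusted p = 0.222), with 3 higher and 6 lower adjusted over the list alone. Over all genes TFF1 rose and SPDEF, a luminal transcription factor, fell by 0.78. The 3' minus 5' difference of GAPDH, a measure of RNA integrity, was 0.80 and 0.84 on the arrays numbered 1, and 0.57 and 0.73 on those numbered 2.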

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

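The comparison of replicate numbers, the estimated correlation within other settings, and the settings that leave out genes at the lowest value or with identical values, were chosen after seeing the data. For the labels, the 30 genes called became 0 with quantile normalization, equal array medians, the 40% dimmest genes left out or the replicate block (288, 201, 193 and 534 at an unadjusted p below 0.05 by limma), 11 without genes at the lowest value on all arrays, 7 without genes identical within both pairs, and 13 with an unadjusted p below 0.05 and a 2-fold difference. Leaving out 1 array gave 107 to 199 genes, of which 16 to 25 were among the 30, because the spread then rests on 1 pair of arrays. The count stayed between 21 and 40 with the mean of a gene's probe sets, all probe sets, no trend, a robust prior or an adjusted p below 0.10. The 0 lists became 2 with equal array medians and 2 with the replicate block, both times glycolysis, up, and NF-kappaB, down (adjusted p = 0.745 and 0.877 for both with an estimated correlation). Fry called 1. Without 1 array, 1 to 3 lists passed (1 without vehicle replicate 1). The estrogen-induced list was then up without E2 replicate 1 and down without E2 replicate 2, and was called in neither case of a left-out vehicle array. The numbers were then unbalanced between the labels, so these directions follow the difference by number. The labels do not say what a number shares, so numbers were not taken to pair the arrays. The deviations of number 1 from its group mean correlated at r = 0.677 between vehicle and E2 across genes, a hint from 2 pairs. For the numbers, the 146 genes became 4775 with equal array medians (690 higher and 4085 lower, against 104 and 42), 2644 of them at the lowest value on all 4 arrays, where the shift of each array leaves a constant difference. They became 242 without the 40% dimmest genes, 0 with the label group as a block (1586 at an unadjusted p below 0.05), 89 with all probe sets fitted, 33 with a robust prior, 94 without genes identical within both pairs, 439 at an adjusted p below 0.10 and 415 at an unadjusted p below 0.05 with a 2-fold difference. Leaving out 1 array gave 298 to 370 genes. The 7 lists became 15 with equal array medians, without the estrogen-repressed list, and 0 with an estimated correlation, and 5 to 8 without 1 array. PTPRC, a leukocyte gene at the lowest value, changed sign to -0.022 with equal array medians. Of the 8 named genes called by label, 3 to 7 stayed called without 1 array, 2 with a robust prior and 6 to 8 with other probe set choices or no trend. Of the 40 called by number, 4 to 13 stayed called without 1 array. A fit with either block left 1 residual degree of freedom, so its count of 0 genes is weak evidence. Pseudocounts were not run on log2 values. Where no construction is named the cause was not tested. Signal over background limits the dim genes: 34.5% to 35.0% of probe sets lie at the lowest value on each array.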

Other observations

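All tests of explanations in this part were chosen after the results were seen. Beyond the lists, the arrays numbered 2 were higher than those numbered 1 in several genes named by the repeated rule. SERPINB9, a granzyme B inhibitor, rose by 4.06, from 2.34, just above the lowest value of the table, to 6.40 (adjusted p = 0.0202 by limma). LGALS1, galectin 1, rose by 3.37, and CYP27B1, which makes active vitamin D, by 3.16. The transcription cofactor FHL2 rose by 3.08. On the arrays numbered 2, the ETS factor ELF5 fell by 2.55 (adjusted p = 0.0456), and ASB9 fell by 1.94. In the apoptosis regulator list, with a median of 0.04 by number, the anti-apoptotic factor BCL2 rose by 1.08. The interferon response list had a median of -0.13 by number, 10 genes higher and 23 lower, and was not called (adjusted p = 0.118), except with the label group as a block (adjusted p = 0.0375; adjusted p = 0.752 with an estimated correlation). Within it ISG20, an interferon-induced exonuclease, rose by 2.22 and HLA-B, an antigen-presenting protein, by 0.63, while SP110 read -0.50 and was not called. The 4 control probe sets for the interferon factor ISGF3A read -0.89, -1.07, -0.32 and -1.37 by number.

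The wider difference by replicate number than by label was weighed first. A processing difference that depends on signal brightness is argued against, because the estrogen-induced median of 0.79 lay above every one of 10000 random lists matched on mean expression (100th percentile, highest random median 0.22). Crossed labels of vehicle replicate 2 and E2 replicate 1 are a candidate explanation: the estrogen-induced median by number was 0.79 and the estrogen-repressed one -0.38 (that list was not called with equal array medians), with the same signs among the vehicle arrays (0.76 and -0.49) and the E2 arrays (0.81 and -0.59). Cultures that differed by replicate number under the right labels cannot be told apart from this, since the estrogen-induced list differed by 0.049 between labels within number 2 and by 0.00 within number 1, and no record of the cultures was used here. Neither the labels nor the values settle it, and every direction in the text keeps the labels as given.

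The position of the 30 called genes near the lowest value of the table was weighed next, since 96.7% of them had a higher group mean below 3, against 46.2% of all genes. Of the 3 ways to part the 4 arrays into pairs, the labels gave 30 genes, 29 of them below 3, and the numbers gave 146, 59 of them below 3. The third way, which follows neither, gave 10, 9 of them below 3. Calls at the low end thus arose without the labels, more of them by number and fewer by the way that follows neither. Probe sets identical within both pairs but different between them numbered 46 by label, 47 by number and 32 by neither. Counted as genes they were 32, 30 and 11. Exact ties of this kind thus also arose without the labels. Whether ties and near ties at the low end of the scale account for all of those calls by label stays open. With 2 ways giving at least 30 genes, these 3 ways are too few for a share under 0.05, and the 146 genes of the number split point to a structure of the arrays. No biological explanation was tested.

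Added control RNAs gave the following values. Over 22 probe sets for RNAs added before labelling, E2 minus vehicle averaged -0.32 ± 0.40 (SD over probe sets), with 16 lower on the E2 arrays. Their median size of difference was 0.37 by label and 0.17 by number, with 12 separated by label and 5 by number. Over 18 probe sets for RNAs added at hybridisation it was 0.080 by label and 0.090 by number, with 8 probe sets separated each way. Control probe sets for human ribosomal RNA differed in sign by number. Those for the small-subunit RNA read -0.53, -0.18 and -0.45, and those for the large-subunit RNA read 0.11 and 0.05. The remaining large-subunit probe set lay at the lowest value of the table on all arrays. The 3' minus 5' difference of ACTB, a measure of RNA integrity, was 4.58 and 4.18 on vehicle arrays 1 and 2. It was 4.81 and 4.60 on E2 arrays 1 and 2. The difference of ACTB thus separated by label, larger on the E2 arrays, and overlapped between numbers. That of GAPDH overlapped between labels. Within each label both were larger on the array numbered 1. Whether RNA integrity differed by label or by number was not tested.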
